A study of Rattus norvegicus with 6 samples.

How the data were processed

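Genomic DNA of ovarian granulosa cells from 6 female rats or pools (3 control, 3 cadmium; the labels do not say which) was profiled by methylated DNA immunoprecipitation on arrays of 2 colours. Per the labels' protocols, immunoprecipitated DNA was labelled with Cy5 and input DNA with Cy3, the same way on all arrays, and the direction of the ratio rests on these labels. The labels also speak of sequencing and of 4 groups of dams, but only the control and 8 mg/kg groups were analysed here, and the files used here are array scanner output. Per the file headers, Agilent Feature Extraction 11.0.1.1 with a ChIP protocol made the signal intensity values, which are background-subtracted and scaled by a linear dye factor per channel, with no lowess step. The array design follows build rn4, per the file headers. The deposited table holds log2 values for the same probes, and the submitters' processing notes name limma as the only tool. Each of its columns correlated at 0.874 to 0.882 with the same array's scanner log2 ratio, in the direction of Cy5 over Cy3. Its column medians lay between -0.034 and 0.027. Neighbouring probes correlated at 0.783 to 0.801 in it and at 0.301 to 0.372 in the scanner ratios, so the table looks smoothed along the genome; how it was scaled, centred and smoothed is not given in the sources used here.

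Log2 ratios of Cy5 over Cy3 were taken from the processed intensities and centred on each array's median, without loess or quantile steps, since most probes of such an array carry signal. Control spots were left out. Probes were kept where the input was well above background on all 6 arrays (153335 probes) and no array flagged either channel as an outlier, which left 132042 of 172669. This handling of outliers was settled after fits of another reading had been seen: at first, outlier spots were set missing on their own array, and no tile passed. A tile mean then averages different probes on different arrays, which was the reason for the change; with each probe's mean removed first, that reading gives 1 tile (adjusted p = 0.0364). Both results are given. The length of gap that separates tiles, the 2-fold level used to count enriched tiles, the 5 Mb windows, the classes by probe length and place in the tile, the equal-spread scaling and the probe length correction were also chosen after the data had been seen. No 2 arrays shared a value for any probe, so none was counted as a duplicate.

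The design called for promoters of named genes. The files give only positions in build rn4, and the gene table used here is of another assembly, so probes could not be assigned to genes. Tiles were instead made of probes whose starts lay no more than 1000 bp apart, which gave 16174 tiles. Tiles with at least 3 kept probes were tested (median 7 probes, 1666 bp). This departs from the design, which fell back on the identifiers in the files; these name single probes. The gene lists, the markers of other cell types, the classes by CpG content and the distance to transcription starts were therefore not analysed here.

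Tile means and single probes were compared between groups with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (with version 1.17.8 of the package data.table), two-sided, with Benjamini-Hochberg adjustment over all tiles or all probes at a threshold of 0.05 and no covariate. Runs were at least 3 neighbouring probes, with gaps up to 500 bp, unadjusted p under 0.05 and the same sign. Each channel was also fitted alone. Named tiles were the 8 with the largest difference in each direction among those that passed and whose groups did not overlap, filled by the smallest unadjusted p among non-overlapping tiles with at least 4 probes; of runs, the 5 with the most probes and then the largest mean difference in each direction were named. The tile on chromosome 1 from 185709022 to 185710720, the probes on chromosomes 11 and 17 and the interval on chromosome 20 were singled out after their values were seen. Class means were compared by exact permutation. The number of arrays limits the precision, and p-values measure the spread between these samples.

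The steps were tested on simulated data with the noise of the real tiles and 200 changed tiles among 15846. The noise was drawn independently for each array, without scan batches or an array of narrower spread. With fewer changed tiles the adjustment is stricter, so recovery in the real arrays can be lower. For the comparison of cadmium against control, 10% of 50 tiles changed by 0.5 (log2) were recovered at adjusted p under 0.05, 82% of those changed by 1, and 100% of those changed by 1.5 or 2, with 5.19% false calls. Scan batches were taken from the headers. Alternatives covered the normalization, background correction, filters on dim and outlier spots, the tile rule, moderation, array weights, the replicate number and scan batch as blocks, each array left out and the deposited table. For normexp, median spot and background signals were used with an offset of 50, as mean spot signals were not used here.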

Results

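DNA methylation was profiled in ovarian granulosa cells, the cells that surround the oocyte and make oestradiol, from adult female offspring of Sprague Dawley rats. The dams had received water (control, 0 mg/kg) or cadmium chloride (8 mg/kg body weight) by gavage from gestation day 1 to 21, and the offspring were sampled at postnatal day 56. There were 3 arrays per group, described in the labels as biological replicates. Whether an array holds 1 animal or a pool, and whether the animals came from separate litters, is not given in the sources used here. On each array, methylated DNA captured by immunoprecipitation was hybridised together with input DNA to a promoter tiling array of 172669 probes, so that the log2 ratio of both signals measures relative methylation. Probes were grouped by position into 16174 promoter tiles, and 15846 tiles with at least 3 usable probes were tested. The tiles carry positions in the rat build rn4 and no gene names, so tiles are named here by position, and the gene lists chosen before the data were examined were not tested.

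The arrays differed in brightness and in the spread of their ratios. The median background-subtracted input signal was between 78.2 and 132.1 on 5 arrays and 327 on cadmium replicate 2. The input signal was well above background for 89.7% to 98.2% of probes and the immunoprecipitated signal for 74.1% to 77.7%. The standard deviation of the tile ratios was 0.776 on cadmium replicate 2 and 1.06 to 1.12 on the other 5 arrays. Tile ratios correlated across tiles at r = 0.982 to 0.991 among those 5 arrays, and at r = 0.945 to 0.957 between them and cadmium replicate 2. Tiles are not independent replicates, so these r values describe the arrays only. Cadmium replicate 2 was scanned alone, control replicates 1 and 2 with cadmium replicate 1 (batch 2), and control replicate 3 with cadmium replicate 3 (batch 3).

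**Figure D1:**
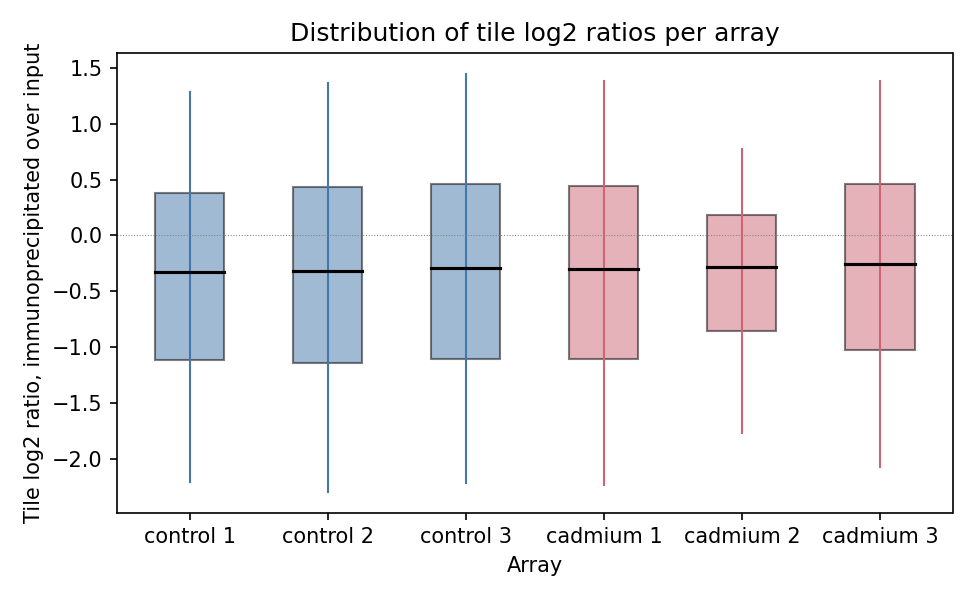
Distribution of tile log2 ratios (immunoprecipitated over input, y axis) on each of the 6 arrays (x axis), over 15846 tiles. Boxes span the middle quartiles with the median as a black line, vertical lines run from the 5th to the 95th percentile, and cadmium 2 has the narrowest distribution (SD 0.776).

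The pattern of tile ratios was shared between groups, though it cannot be read as methylation alone. The ratio also followed probe length, with a median of 1.21 for probes of 45 bases and -2.10 for probes of 60 bases. Of the 15846 tiles, 271 (1.71%) were enriched over 2-fold above the array median on all 6 arrays, and 2909 (18.4%) were depleted over 2-fold on all 6. In the control group alone, 1382 tiles were enriched over 2-fold on all 3 arrays, and 271 in the cadmium group. With cadmium replicate 2 left out, 1322 tiles were enriched on all 5 remaining arrays, so that array set the lower count of the cadmium group. Chromosome 19 had the highest mean tile ratio in controls (0.056 ± 0.033, SD, n = 3) and the X chromosome the lowest (-0.67 ± 0.014, SD, n = 3). In cadmium offspring the values were 0.051 ± 0.095 and -0.62 ± 0.053 (SD, n = 3).

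The main comparison asked whether cadmium exposure of the dam during pregnancy changed promoter methylation in the granulosa cells of the adult offspring. A single tile passed the test, on chromosome 1 from 215580110 to 215581847 (build rn4, 8 probes). Its log2 ratio was -1.28 ± 0.080 in control and -0.19 ± 0.028 in cadmium offspring (SD, n = 3 each). The difference of 1.09 (SE 0.11, 95% confidence interval 0.85 to 1.33) is 2.13-fold and lay in the same direction on 3 of 3 cadmium arrays (limma, adjusted p = 0.0467). Within scan batches the difference was 1.13 in batch 2 and 1.03 in batch 3. The immunoprecipitated signal of this tile differed little between groups (-0.18, SE 0.090, limma adjusted p = 0.999). Its input signal was 2.43-fold higher in controls, a log2 difference of -1.28 (SE 0.090, limma adjusted p = 0.00441), so the difference in the ratio lay in the input DNA. With outlier spots set missing on their own array, which was fitted first, no tile passed (limma, 494 at an unadjusted p under 0.05). This tile then had a difference of 1.28 (SE 0.14, adjusted p = 0.136), and leaving out the whole probe became the main setting after both results had been seen. The tile passed with missing spots once probe means were removed (limma adjusted p = 0.0364) and with outlier spots kept (0.0207). The call was also lost (adjusted p 0.0700 to 0.879 in limma) without a filter on dim probes, with both channels above background, with medians of probes, with equal spread of the arrays, and without any 1 of control replicates 1, 2 and 3 and cadmium replicates 1 and 3.

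**Figure D2:**
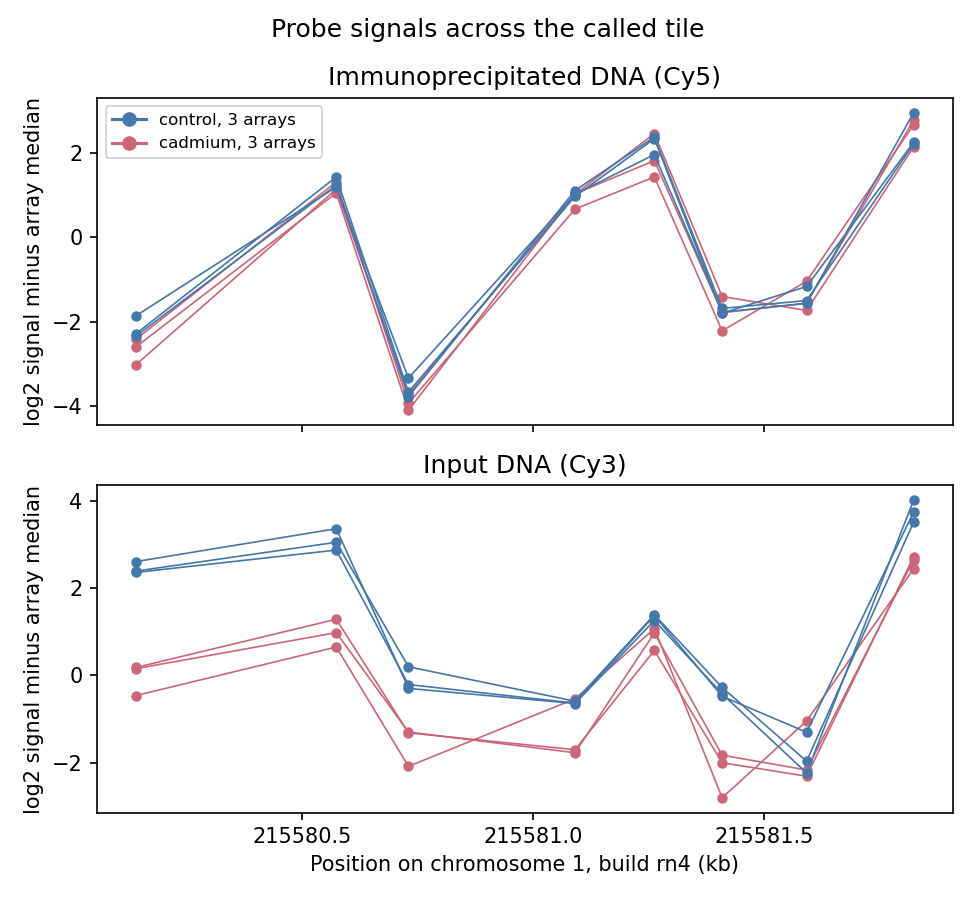
Signals of the 8 usable probes in the tile on chromosome 1 from 215580110 to 215581847 (x axis, position in build rn4, kb), as log2 signal minus the array median (y axis), for immunoprecipitated DNA (top) and input DNA (bottom). Each line is 1 array; input signals were lower in the cadmium arrays by 1.28 on average over the tile, and immunoprecipitated signals by 0.18.

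The other tiles named by the rule fixed in advance did not pass this test. With scan batch as a block, all 8 tiles named as higher in cadmium offspring passed (limma adjusted p 0.000137 to 0.0453) and none of those named as lower, and with it as a random block 5 of the 8 higher passed (adjusted p up to 0.0717). With array weights all 8 higher tiles passed (limma adjusted p up to 0.00998), and 2 of those named as lower (0.0286 and 0.0488). All these tiles were chosen from the same arrays for a small p and groups that did not overlap. That choice fixes their direction within each batch that held both groups, so passing in these fits is no separate support. Among the 8 named tiles higher in cadmium offspring, differences were between 0.62 and 1.09, and adjusted p of the 7 that did not pass reached 0.856 (limma). Their control ratios were between -3.42 and -1.28. Tiles at such levels were higher in cadmium offspring in general, with a median difference of 0.27 at control ratios under -2 and 0.16 from -2 to -1. Without cadmium replicate 2 these medians were 0.12 and 0.064. A tile on chromosome 7 from 142756446 to 142758125 had the next smallest p. Its ratio was -1.66 ± 0.034 in control and -0.59 ± 0.20 in cadmium offspring (SD, n = 3 each, limma adjusted p = 0.110), and the difference was 0.97 within batch 2 and 0.95 within batch 3. It passed in 10 of 32 other settings. In all 8 of these tiles the input signal was lower in cadmium offspring, with a median difference of -0.74, against a median of 0.052 for the immunoprecipitated signal. In 7 of the 8, the input difference was larger than that of the immunoprecipitated signal. Among the 8 named tiles lower in cadmium offspring, differences were between -0.71 and -0.31 and none passed (limma adjusted p = 0.856 for each). A tile on chromosome 1 from 243837922 to 243839314 had the lowest difference, with ratios of -1.42 ± 0.34 in control and -2.13 ± 0.30 in cadmium offspring (SD, n = 3 each), a difference of -0.74 within batch 2 and -0.14 within batch 3. A tile on chromosome 11 from 57925757 to 57927430 had -0.11 ± 0.098 and -0.50 ± 0.074 (-0.30 within batch 2 and -0.51 within batch 3), and there the immunoprecipitated signal carried the difference (-0.37, against 0.017 for input). In the tile on chromosome 1 the input difference was the larger one (0.92, against 0.22), as in 4 of these 8 tiles.

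At an unadjusted p under 0.05, 565 tiles differed where chance gives 792, and 517 of them (91.5%) were higher in cadmium offspring. Of the tiles under this threshold, 326 of 385 (84.7%) were higher after loess, 224 of 362 (61.9%) after quantile normalization and 73 of 151 (48.3%) with equal spread of all arrays. The share was 36 of 193 (18.7%) after normexp background correction, and 129 of 258 (50%) in the deposited value table, which differs in more than its scaling. With 1 array left out it was between 76.8% and 94.9%. The difference between groups fell as the control ratio rose (r = -0.80 across tiles). The control ratio enters both quantities with opposite sign, which pulls r below 0, as does the narrower spread of cadmium replicate 2. This r is therefore a description only. The median difference was 0.27 at control ratios under -2 and -0.35 at those over 2, and 0.12 and 0.0068 without cadmium replicate 2. The groups did not overlap in 1620 tiles (10.2%), where chance gives 10%. The median width of the confidence interval on either side of a tile's difference was 0.31. With scan batch as a block, in which cadmium replicate 2 has no partner and carries no weight, 24 tiles passed and all 24 were higher in cadmium offspring (limma). In fits of each channel over all 6 arrays without a block, input signals were lower in cadmium offspring in 24 of these 24. The input difference was larger than that of the immunoprecipitated signal in 17 of these tiles, and 7 of them lay on chromosome 20. With scan batch as a random block, 6 tiles passed. Without cadmium replicate 2 and without a block, 3 tiles passed. With any 1 of the other arrays left out, 0 passed (limma), and 216 to 1603 had an unadjusted p under 0.05.

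At the level of single probes, none of 132042 passed (limma, lowest adjusted p = 0.105), and 4134 had an unadjusted p under 0.05 where chance gives 6602. Of these, 3541 (85.7%) were higher in cadmium offspring. The share was 71.5% after loess, 51.7% after quantile normalization, 31.9% after normexp background correction, 42.1% with equal spread of all arrays and 46.7% in the deposited value table. The probe with the smallest p lay on chromosome 17 from 12594279 to 12594325. Its log2 ratio was -1.11 ± 0.10 in control and 2.50 ± 0.55 in cadmium offspring (SD, n = 3 each), while its immunoprecipitated signal differed by -0.023 and its input signal by -3.64. The median width of a probe's confidence interval on either side was 0.70.

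Runs of at least 3 neighbouring probes with an unadjusted p under 0.05 and the same sign numbered 14, and all 14 were higher in cadmium offspring. With normexp background correction 9 of 12 runs were higher, and 34 of 61 were in the deposited value table. The longest held 4 probes and lay on chromosome 8 from 54425939 to 54426622, chromosome 20 from 2648023 to 2648547 and chromosome X from 93457167 to 93458010. Their mean differences were 0.98, 0.97 and 0.94, at control ratios of -4.40, -3.87 and -3.88, far below the array median. The immunoprecipitated signal rose more than the input fell on chromosome 8 (0.80 against -0.19) and on chromosome X (0.70 against -0.25), whereas on chromosome 20 the input difference was the larger one (0.37 against -0.61). The next runs by the naming rule lay on chromosome 1, from 215580110 to 215580759 inside the tile that passed, with a mean difference of 1.70, and from 185710153 to 185710720, with 1.69. In both, the input signal carried the difference (-2.03 and -1.65). With probes well above background in both channels, there were 2 runs, with scan batch as a block 34, of which 29 were higher, and after quantile normalization 4. Leaving out control replicate 1 or 2 gave 3 runs each, control replicate 3 gave 9 and cadmium replicate 1 gave 50.

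**Figure D3:**
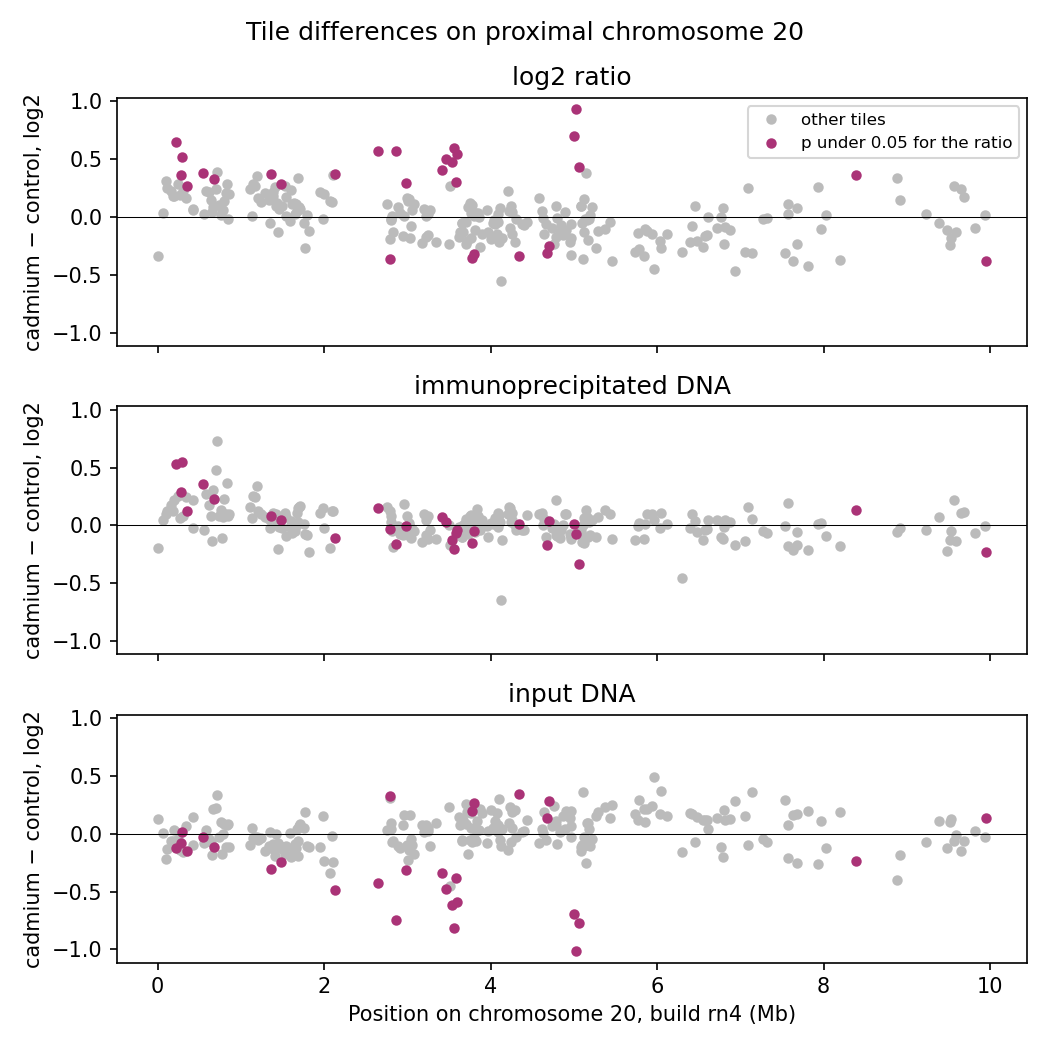
Difference of cadmium minus control (y axis, log2) for each tile on the first part of chromosome 20 (x axis, position in build rn4, Mb), for the ratio, the immunoprecipitated DNA and the input DNA. Coloured points are tiles with an unadjusted p under 0.05 for the ratio; within the first 5 Mb these are 25 of 188 tiles.

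Mean enrichment was also compared between groups of probes and chromosomes, as differences between group means with an exact two-sided permutation test, for which 0.1 is the smallest p that 3 arrays against 3 can give. Tiles on the X chromosome lay below autosomal tiles by a mean of -0.32 ± 0.015 in control and -0.29 ± 0.061 in cadmium offspring (SD, n = 3 each, exact p = 0.8). That difference between groups of 0.024 was -0.032 in batch 2 and 0.020 in batch 3, within the spread between replicates. Probes of 60 bases had a mean ratio of -2.38 ± 0.041 in control and -2.17 ± 0.19 in cadmium offspring (SD, n = 3 each, exact p = 0.1, adjusted p = 0.5 over 5 classes). The difference of 0.22 was 0.064 in batch 2 and 0.15 in batch 3, and it turned to -0.15 with equal spread of all arrays. Probes of 45 bases had 0.77 ± 0.040 and 0.67 ± 0.23 (SD, n = 3 each, exact p = 0.8). Without cadmium replicate 2, the difference was -0.0096 for X minus autosomes, 0.11 for probes of 60 bases and 0.026 for probes of 45 bases, against -0.11 for the last with all arrays; without control replicate 1, 2 or 3 or cadmium replicate 1 or 3, that for probes of 60 bases was 0.19 to 0.30. No chromosome's mean differed by more than 0.058 between groups, and 3 of 22, unplaced sequence counted as 1, reached the smallest possible exact p of 0.1.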

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

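The tests of the 8 named tiles were chosen after the result was seen. The input channel, meant only as the reference of the ratio, differed between groups at single places. In that channel alone, 1 of 15846 tiles and 2 of 132042 probes passed (limma). At an unadjusted p under 0.05 there were 247 tiles and 2801 probes, fewer than the 792 and 6602 that chance gives. A probe on chromosome 17 from 12594279 to 12594325 had 12.5-fold more input signal in control than in cadmium offspring (adjusted p = 0.0273), and a probe on chromosome 11 from 56587996 to 56588040 had 6.49-fold more (adjusted p = 0.0369). The tile on chromosome 1 from 215580110 to 215581847 had 2.43-fold more (adjusted p = 0.00441). In the immunoprecipitated channel alone, 0 tiles and 0 probes passed, with 496 tiles and 3839 probes under an unadjusted p of 0.05, also fewer than chance gives.

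Among the 8 named tiles higher in cadmium offspring, a methylation change with equal input DNA is argued against, for the set, by the median input difference of -0.74. The tile on chromosome 7 from 7924030 to 7925571 went the other way, with 0.51 for the immunoprecipitated signal against -0.12 for input. A shift of signals by scan batch cannot be weighed from these tiles. They were chosen for groups that did not overlap, which places cadmium above control within each batch that held both groups. With scan batch as a block, adjusted over all tiles, the 8 differences were 0.52 to 1.09 and all 8 passed (limma adjusted p 0.000137 to 0.0453). As a random block 5 of 8 passed, with differences of 0.54 to 1.09. Deletions or sequence variants under the probes would lower both channels alike, and these tiles cannot decide on them. In probes well above background in both channels, the immunoprecipitated signal showed a median share of -0.014 of the input difference. In 0 of 8 tiles was the share as much as 0.5. A change of both channels cancels in the ratio by which the 8 were chosen, so the choice itself favoured a low share. What lowered the input signal alone stays open; exposure and anything else that differed between the groups, such as DNA differences joined to methylation differences, were not tested apart.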

How the results depend on the processing

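Alternatives were fixed before the data were examined except those said to be added later. For promoter tiles (1 call), the planned settings gave 3 calls after quantile normalization and in the deposited value table, 2 with trend and robust moderation, 24 with scan batch as a block and 106 with array weights. They gave 0 without a filter on dim probes, with both channels above background, with the plain t-test, with medians of probes and with the replicate block. At an unadjusted p under 0.01 there were 78 tiles. Leaving out 1 array gave 0 to 3 calls. Added later were outlier spots missing per array (0 calls, 494 tiles at an unadjusted p under 0.05; 1 call with probe means also removed and 1 with outliers kept), of which the reading with missing spots was fitted before the main one, tile gaps of 500 bp (2), equal spread of arrays (0; 3 without cadmium replicate 2), quantile normalization without that array (3), probe length correction with replicate block (0), scan batch as a random block (6) and both channels above background without cadmium replicate 2 (4). The tile on chromosome 1 from 215580110 to 215581847 was called in 19 of 32 other settings. These include the main fit at a threshold of 0.1, which cannot lose the call. The tile's difference was 0.80 to 1.55 and its adjusted p 1.09e-05 to 0.879 (limma or plain t-test). The tiles on chromosome 7 from 142756446 to 142758125 and on chromosome 1 from 185709022 to 185710720 were called in 10 and 9. The cause of these changes was not tested.

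For probes (0 calls), loess, quantile normalization, no filter on dim probes, both channels above background (with and without cadmium replicate 2) and trend and robust moderation gave 1 call each, and array weights 3; leaving out 1 array gave 0 each time. Runs (14) numbered 4 after quantile normalization, 2 with both channels above background (5 without cadmium replicate 2, added later), 61 in the deposited table, 34 with scan batch as a block, 3 at a length of at least 4 probes, 0 at 5, 3 at a probe p under 0.01, and, added later, 2 with equal spread and 8 with probe length correction. Leaving out 1 array gave 3 to 50 runs. The cause was not tested. Replicate numbers did not pair the arrays (correlations of deviations -0.19, -0.10 and 0.37 for equal numbers), and the replicate block left 14 runs and 0 probes.

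Differences of class means changed sign in places, none past a threshold. For X minus autosomes they were -0.018 with equal spread and -0.0097 after quantile normalization (-0.0096 to 0.049 with 1 array left out). For probes of 60 bases they were -0.0050 with normexp, -0.15 with equal spread and -0.0027 after quantile normalization. For probes of 46 to 59 bases the value was -0.017 with equal spread, for tile centre minus edges 0.0049 and 0.0011, and for probes of 45 bases 0.026 without cadmium replicate 2 (-0.18 to 0.026). The cause was not tested. Not run were correction for GC content (also with the replicate block), a window around transcription starts, removal of shared probes and all tests of gene lists, which need sequences or gene positions in build rn4. The immunoprecipitated signal was well above background for 74.1% to 77.7% of probes, and ratios of the others rest on background.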

Other observations

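The windows, the comparison of both channels and the tests of the excess of higher tiles were chosen after the result was seen, although leaving out cadmium replicate 2 and requiring both channels above background were planned settings; the test of input spread and the splits of the arrays were written before. Tiles with an unadjusted p under 0.05 were not spread evenly over the genome. Of 289 windows of 5 Mb, 8 held more of them than the rest (Fisher's exact test, two-sided, Benjamini-Hochberg over the windows), though neighbouring tiles are not independent. The test took no account of the ratio level, although tiles at low control ratios were higher in cadmium offspring in general. Windows were tested on the main fits only, not with equal spread or without cadmium replicate 2. Windows that merely hold many tiles of low ratio can therefore not be told from local differences. The first 5 Mb of chromosome 20 came first, with 25 of 188 tiles (13.3%) against 3.57% of all tiles (adjusted p = 4.11e-06), 19 higher and 6 lower in cadmium offspring. The next were chromosome 4 from 85 to 90 Mb (9 of 38 tiles) and chromosome 1 from 160 to 165 Mb (20 of 188), where all were higher in cadmium offspring. In the input channel alone, the window on chromosome 20 was the only one of 289 to pass (17 tiles, adjusted p = 1.8e-06), and in the immunoprecipitated channel alone none passed.

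A hypothesis for the interval on chromosome 20, which in the rat holds the major histocompatibility complex, known for its sequence diversity, is that the animals differed in DNA there. For differences among the animals of a group, the median spread of the input signal within groups was compared over all 188 tiles of the interval. It was 0.96 of that of other tiles (permutation p = 0.775), so most of the interval had no wider spread. A median cannot show differences in a small part of the tiles, nor can an array show those inside a pool, so such differences stay open. For the 25 tiles as a set, a methylation change with equal input DNA is argued against. The immunoprecipitated channel differed more than the input in only 24% of them. The input differed more in 76%, against 47.6% elsewhere (Fisher's exact p = 0.0069). The 24% include tiles near the start of the chromosome, for which such a change stays open. Those starting at 213019 and 290138 had 0.53 and 0.54 for the immunoprecipitated signal, against -0.12 and 0.013 for input. Copy losses or variants shared by the animals of a group would move both channels alike, and these data cannot decide on them. They were looked at in the 17 tiles under an unadjusted p of 0.05 for input, in probes well above background in both channels. There the immunoprecipitated signal showed a median share of 0.045 of the input difference, with single tiles from -5.453 to 1.175. These tiles were chosen for a small p in the input channel. The interval was found through the ratio, in which a change of both channels cancels. Both choices favoured a low share. What moved the input signal therefore stays open, with exposure untested. Of the 10 splits of the 6 arrays, too few for a share under 0.05, 2 gave a share as large. The other, also 13.3%, separated the arrays of scan batch 2 from the rest. With scan batch as a fixed block 6 tiles of the interval passed, but none with it as a random block. The tile from 5020921 to 5022252, just past the edge of the interval, passed with both (limma adjusted p = 0.001665 and 0.02132). It is among the named tiles, which were chosen for a small p and groups that did not overlap.

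The excess of higher tiles (517 of 565) was seen without cadmium replicate 2 as well (87.2%), which argues against that array alone as its source. Unequal spread of the arrays stays open: with equal spread 48.3% were higher over all 6 arrays, but 85.8% without cadmium replicate 2. Immunoprecipitated signal near background stays open too, as 68.4% were higher when both channels were well above background. Quantile normalization gave 55.6% without that array. Exposure itself stays open and was not tested apart from these.

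Other splits of the arrays gave larger counts in part. The real split called 1 tile and the highest other split 0. At an unadjusted p under 0.05, 5 of the 10 splits gave as many tiles (565 in the real split, 1327 in the highest other), and 4 as many probes (4134, 10500). For runs, 3 did (14, 57). The highest was each time the split that follows the scan batch, which points to a structure of the arrays by batch. With 10 splits no share under 0.05 can be had. With scan batch as a block, exchanging labels within batches gave 6 arrangements; the real one called 24 tiles and the highest other 0, while at an unadjusted p under 0.05 they gave 1296 and 1119. These arrangements too are too few for a share under 0.05.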
